A study of Mus musculus with 6 samples.

How the data were processed

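Bulk RNA sequencing was done on mesenchymal stem cells sorted from mouse quadriceps muscle as cells positive for a collagen 1 promoter-driven green fluorescent protein and for the surface marker Sca-1, the product of Ly6a. Per the series' design text, the cells came from 6 male mice, were used at passage 4 and were kept for 72 hours in medium conditioned by bone marrow-derived macrophages. Those macrophages were either control cells or cells made senescent by hydrogen peroxide, applied at 300 µM for 3 hours and again in the same way 3 days later, followed by 14 days of culture. Each conditioned medium was collected over 48 hours, collected again, and the collections were pooled. The labels give 3 libraries for each medium, and groups and replicate numbers were taken from the sample titles. About 600 ng of RNA per sample was sequenced on an Illumina NovaSeq 6000 with paired reads of 150 bp, per the labels' protocols.

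The deposited table holds estimated counts per Ensembl gene for the 6 libraries, not normalized. STAR, DESeq2 and the mouse build mm39 are named, with no role or order, per the submitters' processing notes. The counting tool, the annotation release and the strand setting are not given in the sources used here, so genes that overlap on opposite strands or that have near-identical copies carry some uncertainty. Between 70.3% and 72.8% of a library's values lay within 0.01 of a whole number and the rest were fractional. Every one of the 18124 listed genes had at least 10 counts summed over the 6 libraries, so a gene that is not listed may have had fewer counts or may be missing from the annotation used, and no value is given for it. Library totals ran from about 17228200 to 21659400 estimated counts. The values were rounded to whole numbers before testing.

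Gene symbols came from GENCODE release M21, an annotation of the older mouse build GRCm38, matched on the Ensembl identifier. A symbol was found for 18092 of the 18124 identifiers (99.8%), and 32 had none. Because mm39 and GRCm38 differ, no coordinates are given. The most abundant feature, an Ensembl gene with no symbol in that annotation, took 2.78% to 5.29% of a library's counts and stayed in the library sizes. In the same annotation, exons of 8 of the 79 named genes were overlapped over more than 10% of their length by exons of another gene: Mt2, Slc16a6, Sqstm1, Kif20a, Hexa and Hsp90b1 on the opposite strand, and Fdps and Gbp7 on the same strand.

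The main test was the quasi-likelihood F-test of edgeR 4.0.16 with robust dispersion estimates, TMM scaling factors and edgeR's expression filter, run in R 4.3.3 with the medium as the only term. It was two-sided, with Benjamini-Hochberg adjustment over the 14644 genes tested and a threshold of 0.05 on the adjusted p. Log2 fold changes are senescent over control macrophage medium, and their standard errors were taken as the absolute log2 fold change divided by the square root of F. Expression levels are CPM (counts scaled by the TMM-adjusted library size), given as mean ± SD of 3 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and adjustment over the 30 lists. Camera compares a list's genes with all other tested genes. Counts of changed list members use the adjustment over all 14644 genes, and counts adjusted over the list alone stand beside them.

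The design, the 30 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between the libraries of both groups, leaving out predicted genes without a proper name. It added the 2 members of each list with the smallest adjusted p and a fixed set of identity and senescence genes (among them Col1a1, Ly6a, Pdgfra, Cdkn1a, Cdkn2a, Cdkn2b, Lmnb1, Il6 and Mki67), which gave 79 genes. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, other thresholds, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and the rotation test fry. Removal of trends with GC content and transcript length, known for 14625 of the tested genes (99.9%), and removal of the most abundant feature were added after the data were seen.

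The test was first run on simulated counts for the 14644 genes, drawn from the means and sizes of these libraries, with 50 genes changed at each of 4 fold sizes. For this comparison it recovered 50% of the 1.2-fold changes, 70% of the 1.5-fold, 92% of the 2-fold and 98% of the 4-fold changes, with 10 false calls among 14444 unchanged genes. Far fewer genes were changed than were called in the data, which makes the adjusted threshold harder to reach, so these shares need not hold for the data. Camera called the 1 changed list and 0 of the 29 unchanged lists in simulated data, in which genes vary independently of each other. The replicates of each medium were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was 2.70 to 8.38 over the 6 pairs, a mean that few abundant genes can raise, and its median over genes was 0.887 to 1.22, where sampling noise alone gives 0.455. No pair of libraries agreed within sampling noise by either measure, as far as the test holds for estimated counts.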

Results

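Mesenchymal stem cells from mouse quadriceps were cultured for 72 hours in medium conditioned by control or by hydrogen peroxide-treated, senescent bone marrow-derived macrophages, and their RNA was sequenced in 3 libraries per medium. The cells belong to the collagen-producing, Sca-1-positive stromal population of muscle. The comparison asked how products of the senescent macrophages alter gene expression in these cells; the labels do not say whether control macrophages were cultured as long as the senescent ones, so differences between the media need not come from senescence alone. The control libraries held about 17232700, 21225800 and 17228200 estimated counts and the senescent-medium libraries 21659400, 19420800 and 21089500. Nothing in the labels says that the libraries of a group came from separate animals, cell isolates or batches of medium, so p-values measure the spread between these libraries, which may be technical.

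In senescent macrophage medium cell cycle and cholesterol synthesis genes were lower, and interferon-stimulated, amino acid stress, glycolytic, lysosomal and collagen genes were higher, as were the metallothionein genes Mt1 and Mt2. Camera called 13 of the 30 gene lists with a preset correlation between genes. With an estimated correlation 5 held, namely the G2 and M phase, S phase, ATF4, endoplasmic reticulum and glycolysis lists. That setting also rests on the few residual degrees of freedom of 6 libraries, so a lost call need not mean correlated genes. The matrix protease list lost its call (camera adjusted p = 0.226) at an estimated correlation of 0.0071, below the preset 0.01. Of 14644 genes tested, 7251 (49.5%) passed the threshold, 3607 higher and 3644 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With libraries scaled by their totals alone, 2589 genes were higher and 4813 lower. Most changes were small. The median absolute log2 fold change of the called genes was 0.37, 5238 of them (72.2%) changed by less than 1.5-fold, and 385 genes were higher and 479 lower with an absolute log2 fold change of at least 1. The first principal component of log2 CPM, with 64.0% of the variance, separated the media, and the second held 10.7%. Spearman correlations across genes were 0.996 to 0.997 within a medium and 0.981 to 0.982 between media. The CPM values of the 3 libraries per medium did not overlap for 8172 genes (55.8%), where chance gives 10%.

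**Figure D1:**
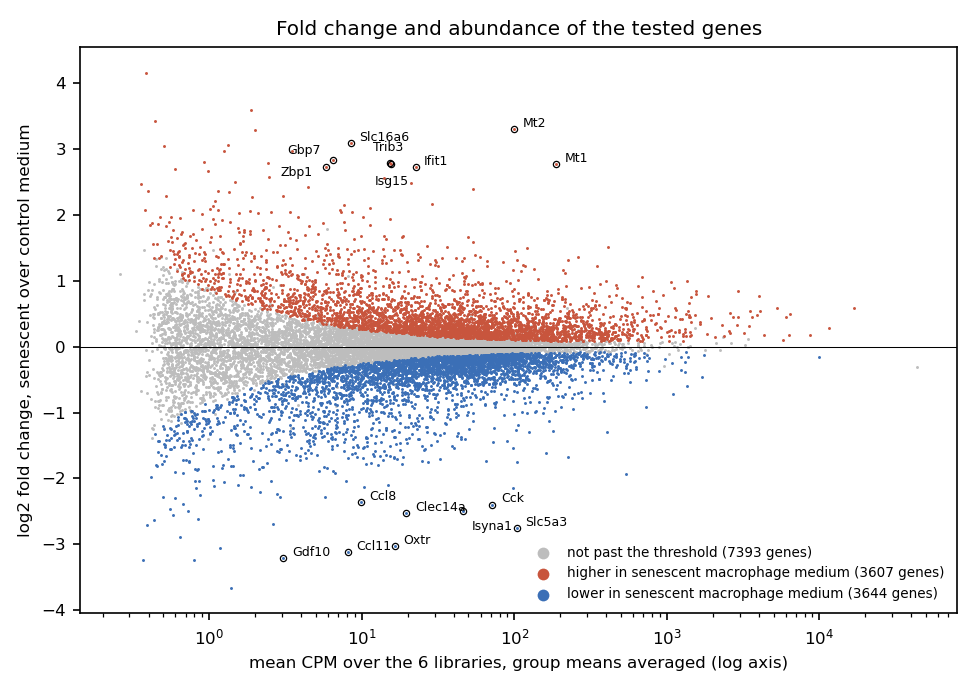
Each point is 1 of the 14644 tested genes, with its mean CPM on a log axis and its log2 fold change, senescent over control macrophage medium (3 libraries each). Red and blue points are the 3607 higher and 3644 lower genes past an adjusted p of 0.05 (edgeR), and circles mark the 8 largest rises and 8 largest falls chosen by the fixed rule.

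Among genes past the threshold with at least 5 CPM in the higher group and no overlap between media, unnamed predicted genes left out, the largest rise was that of Mt2 (ENSMUSG00000031762), a metallothionein that binds zinc and copper. It went from 18.5 ± 3.63 to 181 ± 5.43 CPM, a log2 fold change of 3.30 ± 0.099 (adjusted p = 1.15e-08, edgeR). Here and throughout, ± is the SD of 3 libraries after a CPM value and the SE after a log2 fold change. Its neighbour Mt1 (ENSMUSG00000031765) rose from 47.9 ± 6.26 to 327 ± 11.5 CPM, with a log2 fold change of 2.78 ± 0.076. Slc16a6, a monocarboxylate transporter family member, rose from 1.76 ± 0.0656 to 15.1 ± 1.16 CPM and Trib3, a pseudokinase induced by amino acid stress, from 3.91 ± 0.831 to 26.6 ± 2.22 CPM, with log2 fold changes of 3.09 ± 0.14 and 2.78 ± 0.12. The other 4 of the 8 largest rises were interferon-induced: Gbp7 (2.83), Isg15 (2.77), Ifit1 (2.72) and Zbp1 (2.72). The exons of Mt2 are largely overlapped by an annotated antisense gene, and those of Slc16a6 in part by Amz2 on the opposite strand, so reads of both could be counted together; strand use is not given.

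Gdf10 (ENSMUSG00000021943), a secreted factor of the TGF-beta superfamily, had the largest fall among such genes, from 5.54 ± 0.345 to 0.592 ± 0.121 CPM (log2 fold change −3.20 ± 0.24, adjusted p = 9.88e-13, edgeR). The eosinophil chemokine Ccl11 fell from 14.6 ± 0.721 to 1.68 ± 0.119 CPM and the monocyte chemokine Ccl8 from 16.5 ± 1.2 to 3.21 ± 0.437 CPM, with log2 fold changes of −3.12 ± 0.14 and −2.36 ± 0.13. The oxytocin receptor gene Oxtr went from 29.5 ± 2.71 to 3.64 ± 0.302 CPM (−3.02 ± 0.11) and Cck, which encodes the peptide hormone cholecystokinin, from 121 ± 1.15 to 23.0 ± 1.18 CPM (−2.40 ± 0.052). Slc5a3 (ENSMUSG00000089774), the sodium-coupled myo-inositol transporter, fell from 182 ± 2.75 to 26.9 ± 1.34 CPM (log2 fold change −2.75 ± 0.048, adjusted p = 3.19e-28, edgeR), the smallest adjusted p of all genes. Isyna1, the enzyme that makes myo-inositol phosphate from glucose 6-phosphate, fell with it, from 78.3 ± 5.33 to 13.8 ± 1.04 CPM (−2.50 ± 0.068). The membrane lectin gene Clec14a changed by −2.52 ± 0.097.

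**Figure D2:**
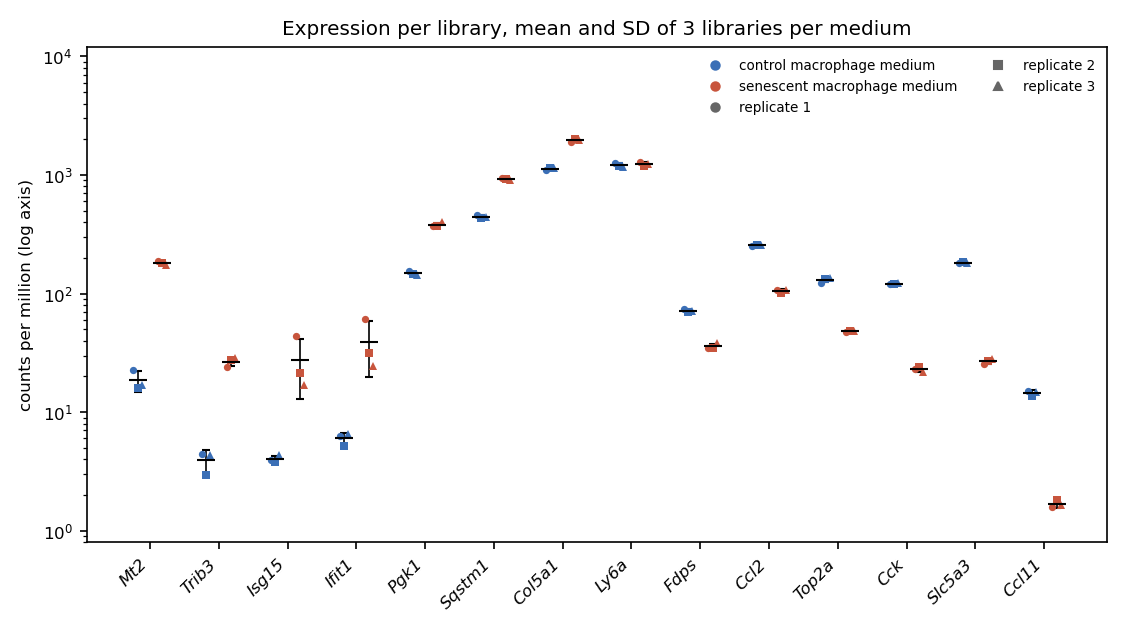
CPM of 14 named genes on a log axis, with each library as a point (circle, square and triangle for replicates 1 to 3), the mean as a bar and the SD over 3 libraries as whiskers. Most genes vary little within a medium, while Isg15 spans 16.8 to 43.8 CPM and Ifit1 24.7 to 61.2 CPM among the senescent-medium libraries.

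Cell cycle genes were lower in senescent macrophage medium. All 35 tested G2 and M phase genes fell, with a median log2 fold change of −1.41 (camera adjusted p = 5.05e-21), and 33 of 35 S phase genes fell, with a median of −0.91 (adjusted p = 1.73e-14). No member of either list rose, and the counts adjusted over the list alone were the same. Top2a, which untangles replicated chromosomes, went from 130.2 ± 6.12 to 48.1 ± 0.446 CPM, a log2 fold change of −1.44 ± 0.047 (adjusted p = 1.90e-21, edgeR), and the mitotic kinesin gene Kif20a changed by −1.37 ± 0.057. The proliferation marker Mki67 fell from 106 ± 7.16 to 38.9 ± 3.66 CPM (−1.45 ± 0.062). Thymidine kinase gene Tk1 changed by −1.79 ± 0.092 and the replicative helicase subunit gene Mcm4 by −1.06 ± 0.059. Both list calls held with an estimated correlation between genes (adjusted p = 0.0373 and 0.0179).

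Interferon-stimulated genes were higher in senescent macrophage medium, by unequal amounts in its libraries. Of 48 tested members 45 rose and 0 fell (48 rose when adjusted over the list alone), with a median log2 fold change of 1.46 (camera adjusted p = 2.57e-13). The call was lost when the correlation was estimated (adjusted p = 0.316 with an estimated correlation); the estimated correlation itself was 0.626. Median log2 values of the list relative to the control mean were 1.89, 1.24 and 1.17 in senescent-medium replicates 1, 2 and 3. Ifit1, which binds viral RNA, went from 6.00 ± 0.693 to 39.1 ± 19.4 CPM (log2 fold change 2.72 ± 0.51, adjusted p = 0.0123, edgeR). The class I antigen-presentation gene H2-D1 rose from 63.4 ± 2.53 to 95.5 ± 4.95 CPM with less spread (0.59 ± 0.049); it belongs to a family of near-identical genes. The macrophage gene Lyz2 also rose (0.80 ± 0.12), while Cd14 fell (−1.14 ± 0.16). Without senescent-medium replicate 1, 44 of 48 members were still higher, and without control replicate 2, 29 of 49 were. Isg15 missed the threshold without control replicate 1, 2 or 3 (adjusted p = 0.0592, 0.0650 and 0.0568, edgeR), and Ifit1 without control replicate 1 or 2 (0.0512 and 0.0579), with log2 fold changes of 2.62 to 2.82 in those fits.

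Genes of amino acid stress, of protein folding in the endoplasmic reticulum and of glycolysis were mostly higher. Of 29 ATF4 and amino acid stress genes, 26 rose and 1 fell (26 and 2 adjusted over the list alone), with a median log2 fold change of 0.57 (camera adjusted p = 2.79e-12). Slc7a5, a subunit of the large neutral amino acid transporter, rose from 26.9 ± 0.163 to 80.6 ± 1.16 CPM (1.58 ± 0.053) and Ero1l, an oxidase of the endoplasmic reticulum, from 63.5 ± 1.79 to 179 ± 5.11 CPM (1.49 ± 0.042). Of 23 endoplasmic reticulum unfolded protein genes, 21 rose and 0 fell (the same adjusted over the list alone), with a median of 0.33 (adjusted p = 2.03e-08). The chaperone genes Hsp90b1 and Hspa5 changed by 0.79 ± 0.033 and 0.76 ± 0.033. Of 35 glycolysis and hypoxia genes, 28 rose and 0 fell (28 and 1 adjusted over the list alone), with a median of 0.65 (adjusted p = 3.55e-12). Pgk1 and Aldoa, both enzymes of glycolysis, rose from 148 ± 5.10 to 378 ± 17.2 CPM and from 714 ± 17.1 to 1413 ± 16.7 CPM, log2 fold changes of 1.36 ± 0.039 and 0.99 ± 0.032. Pgk1 has a near-identical processed copy in the genome. The 3 calls held with an estimated correlation (adjusted p = 0.0179, 0.0322 and 0.0378, in the order given).

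Antioxidant and lysosomal genes were mostly higher. Among 38 NRF2 and antioxidant genes 30 rose and 5 fell, with a median log2 fold change of 0.36 (camera adjusted p = 2.93e-08; adjusted p = 0.250 with an estimated correlation). Srxn1, which repairs oxidised peroxiredoxins, rose from 129 ± 1.97 to 289 ± 13.1 CPM (1.16 ± 0.038), and heme oxygenase gene Hmox1 from 319 ± 18.2 to 611 ± 32.7 CPM (0.94 ± 0.043). The autophagy receptor gene Sqstm1, held by the antioxidant and the lysosome list, rose from 443 ± 13.0 to 923 ± 18.0 CPM (1.06 ± 0.034); part of its exons overlaps Mrnip on the opposite strand. Mt1 and Mt2 are the members with the largest rises of the antioxidant list, although metal ions induce them as well. Of 34 lysosome and autophagy genes 30 rose and 0 fell (31 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 2.02e-10; adjusted p = 0.226 with an estimated correlation). Hexa, a lysosomal hexosaminidase gene, changed by 0.63 ± 0.037. For the antioxidant list the counts adjusted over the list alone were the same.

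Genes of the cholesterol, adipogenic, and osteogenic and chondrogenic lists were mostly lower. Of 24 cholesterol synthesis and uptake genes 23 fell and 1 rose, with a median log2 fold change of −0.67 (camera adjusted p = 9.98e-12; adjusted p = 0.157 with an estimated correlation). Fdps, which makes farnesyl diphosphate, fell from 71.7 ± 2.61 to 35.8 ± 2.01 CPM (−1.003 ± 0.055), and Hsd17b7, a later enzyme of the pathway, from 182 ± 6.23 to 91.8 ± 2.50 CPM (−0.99 ± 0.041). Of 22 adipogenic genes 15 fell and 4 rose, with a median of −0.67 (camera adjusted p = 0.00202; adjusted p = 0.311 with an estimated correlation). The adipogenic transcription factor gene Cebpa went from 206 ± 5.85 to 102 ± 5.04 CPM (−1.01 ± 0.041) and the fatty acid desaturase gene Scd1 from 352 ± 4.55 to 205 ± 3.57 CPM (−0.78 ± 0.034). Of 20 osteogenic and chondrogenic genes 11 fell and 4 rose, with a median of −0.26 (camera adjusted p = 0.0299; adjusted p = 0.226 with an estimated correlation). Alkaline phosphatase gene Alpl fell from 16.1 ± 0.908 to 5.64 ± 0.483 CPM (−1.51 ± 0.11) and Prg4, which encodes the lubricant lubricin, from 472 ± 10.1 to 289 ± 16.5 CPM (−0.71 ± 0.038). The osteogenic and chondrogenic call was also lost with library totals (camera adjusted p = 0.0771) and without senescent-medium replicate 2 (0.0637), and the 4 risen members became 2 with library totals, with DESeq2, and without control replicate 1 or 2. In these 3 lists the counts adjusted over the list alone were the same.

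Collagen genes rose, and other matrix genes moved both ways. Of 18 fibrillar and basement membrane collagen genes 14 rose and 2 fell, with a median log2 fold change of 0.48 (camera adjusted p = 9.97e-06; adjusted p = 0.209 with an estimated correlation). Col1a1, whose promoter marks these cells, rose from 5361 ± 69.8 to 7516 ± 229 CPM (0.49 ± 0.033, adjusted p = 1.27e-13, edgeR). Col5a1 and Col5a3, chains of type V collagen, changed by 0.79 ± 0.034 and 1.35 ± 0.065. Among 23 matrix proteases and their inhibitors 14 rose and 5 fell, with a median of 0.16 (camera adjusted p = 0.0299; adjusted p = 0.226 with an estimated correlation, and 0.0503 without senescent-medium replicate 2). With library totals 10 rose and 7 fell, with a median of 0.084. Cathepsin K gene Ctsk rose from 82.5 ± 3.60 to 186 ± 6.91 CPM (1.17 ± 0.042) and the aggrecan-cleaving protease gene Adamts5 from 779.6 ± 47.3 to 1438 ± 30.7 CPM (0.88 ± 0.037). Of 37 other matrix glycoprotein, proteoglycan and collagen-processing genes 21 rose and 11 fell (21 and 12 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0696), which it passed with library totals (0.0426). P4ha1 and Plod2, which hydroxylate proline and lysine in collagen, changed by 0.71 ± 0.034 and 0.78 ± 0.038. Of 33 TGF-beta targets and myofibroblast contractile genes 10 rose and 15 fell (11 and 15 adjusted over the list alone; camera adjusted p = 0.153), and 4 rose with library totals. Fibronectin gene Fn1 rose from 13457 ± 593 to 20279 ± 915 CPM (0.59 ± 0.038), while the contractile cell gene Lmod1 fell from 28.3 ± 0.421 to 12.1 ± 0.430 CPM (−1.23 ± 0.079). For the collagens and the proteases the counts adjusted over the list alone were the same.

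**Figure D3:**
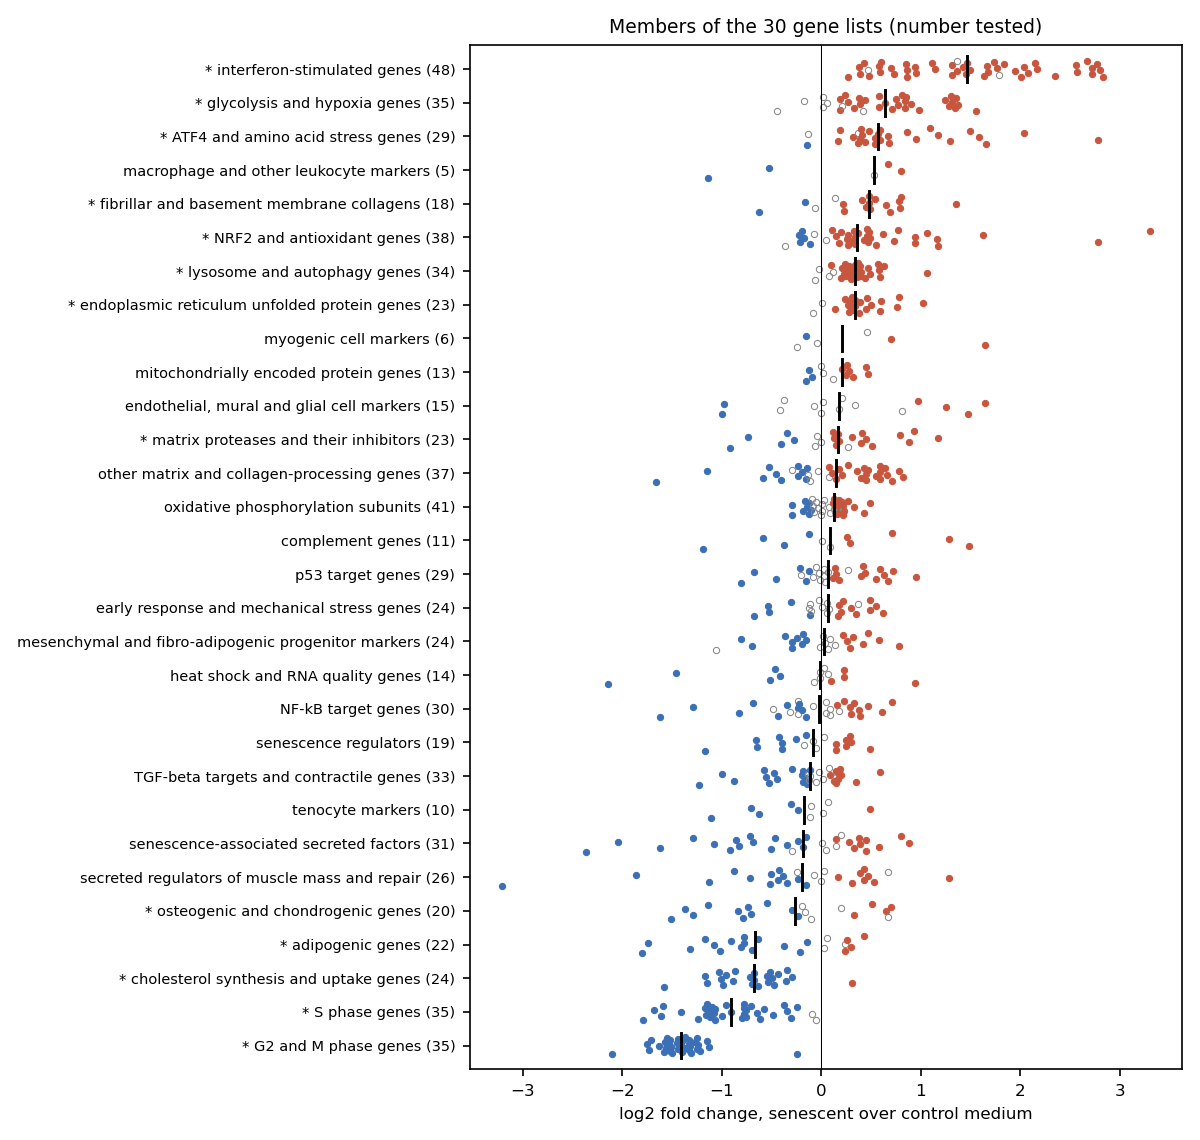
Log2 fold change, senescent over control macrophage medium, of each tested member of the 30 lists, with the number tested in brackets, filled points for members past an adjusted p of 0.05 (edgeR), open points for the others, and a bar at each list's median. Asterisks mark the 13 lists past the threshold in camera with a preset correlation. The medians of the p53, early response and mesenchymal marker lists turn negative with library totals alone, and those of the NF-kB and heat shock lists turn positive under some scalings.

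The lists of senescence genes and of secreted inflammatory factors missed camera's threshold, with members moving both ways. Of 19 senescence regulators 7 rose and 8 fell (camera adjusted p = 0.547). That list was drawn up with no direction assumed for its members, while camera asks for a shift one way. Its miss therefore cannot tell whether a senescence response took place. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, rose from 135 ± 6.88 to 189 ± 5.31 CPM (0.49 ± 0.040, adjusted p = 1.27e-11, edgeR), and Cdkn2b from 104 ± 2.30 to 124 ± 2.82 CPM (0.24 ± 0.041). Cdkn1a, the gene of p21, rose by less (0.15 ± 0.032) and missed the threshold with library totals alone (log2 fold change 0.072, adjusted p = 0.0665, edgeR). The lamin gene Lmnb1 fell from 33.8 ± 2.21 to 21.4 ± 0.293 CPM (−0.65 ± 0.070), as did the inhibitor gene Cdkn2c (−1.17 ± 0.10). Of 31 secreted factors of the senescence-associated secretory phenotype 10 rose and 16 fell (camera adjusted p = 0.183). The chemokine genes Cxcl5 and Ccl2 fell from 242 ± 8.90 to 78.9 ± 2.86 CPM and from 255 ± 1.27 to 105 ± 3.65 CPM, log2 fold changes of −1.62 ± 0.041 and −1.28 ± 0.038. Il6 was low and fell from 8.74 ± 0.418 to 6.91 ± 0.468 CPM (−0.34 ± 0.12, adjusted p = 0.0200, edgeR), a call lost with DESeq2 (adjusted p = 0.0685) and, in edgeR, without control replicate 2 (0.0846) or senescent-medium replicate 1 or 2 (0.0674 and 0.0659). Of 30 NF-kB target genes 10 rose and 10 fell (camera adjusted p = 0.719). In these 3 lists the counts adjusted over the list alone were the same.

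Of 26 secreted regulators of muscle mass and repair, 8 rose and 13 fell (camera adjusted p = 0.183). Inhbb, which encodes an activin subunit, fell from 232 ± 4.57 to 106 ± 0.248 CPM (−1.13 ± 0.037), and Hgf, the growth factor that activates muscle satellite cells, from 267 ± 11.8 to 163 ± 5.45 CPM (−0.71 ± 0.039). Gdf10 is in this list too. Of 29 p53 target genes 13 rose and 6 fell (camera adjusted p = 0.183; 9 rose and 9 fell with library totals), with the smallest adjusted p for Plk2 (0.72 ± 0.045) and the stress sensor gene Sesn2 (0.59 ± 0.042), which the ATF4 list also holds. Of 11 complement genes 5 rose and 4 fell (camera adjusted p = 0.661); Masp1, a protease of the lectin pathway of complement, fell from 146 ± 5.47 to 64.1 ± 2.69 CPM (−1.18 ± 0.045). In these 3 lists the counts adjusted over the list alone were the same.

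Markers of the sorted cells were abundant in both media. Ly6a, the gene of the sorting marker Sca-1, measured 1206 ± 44.7 CPM in control and 1235 ± 46.8 CPM in senescent macrophage medium, a difference within the spread of the libraries (log2 fold change 0.034 ± 0.035, adjusted p = 0.449, edgeR) whose sign depended on the scaling. Pdgfra, a receptor gene that marks fibro-adipogenic progenitors, fell from 265 ± 9.87 to 217 ± 2.06 CPM (−0.29 ± 0.036). Of 24 mesenchymal and fibro-adipogenic progenitor markers 8 rose and 9 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.951). Their median was 0.026 and their mean −0.026, with an upward direction in camera and a median of −0.055 with library totals. Cd248 (0.58 ± 0.033) and Col15a1 (0.79 ± 0.068) rose. Of 10 tenocyte markers 1 rose and 5 fell (camera adjusted p = 0.153), the risen one being the early response gene Egr1 (0.49 ± 0.065).

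Lists of markers of other cell types gave no call in camera. Of 29 macrophage and other leukocyte markers 9 were in the table and 5 were tested, of which 2 rose and 2 fell (camera adjusted p = 0.821). With 1 library left out 1 to 3 rose and 1 to 2 fell, and their median log2 fold change of 0.53 became 0.16 without senescent-medium replicate 1. The lysozyme gene Lyz2 rose from 6.71 ± 0.779 to 11.7 ± 1.33 CPM (0.80 ± 0.12), while Cd14 fell from 7.19 ± 0.468 to 3.26 ± 0.820 CPM (−1.14 ± 0.16). Of 6 tested myogenic markers 2 rose and 1 fell (camera adjusted p = 0.539; 2 fell with library totals or without senescent-medium replicate 3); these were the desmin gene Des, from 1.62 ± 0.245 to 5.15 ± 0.772 CPM, Acta1, from 8.49 ± 1.03 to 13.8 ± 0.612 CPM, and Vcam1 (−0.15 ± 0.035), which stromal cells express too and which was named after its value was seen. Of 15 endothelial, mural and glial markers 4 rose and 2 fell (camera adjusted p = 0.430; 6 rose without senescent-medium replicate 3 or with GC content and transcript length trends removed), with Des again among them and a fall of the smooth muscle myosin gene Myh11 from 15.5 ± 1.81 to 7.78 ± 0.485 CPM. In the tenocyte, leukocyte, myogenic and endothelial lists the counts adjusted over the list alone were the same.

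The early response, heat shock, oxidative phosphorylation and mitochondrially encoded lists gave no call in camera. Of 24 early response and mechanical stress genes 10 rose and 5 fell (camera adjusted p = 0.285), with Klf4 higher (0.49 ± 0.036) and the phosphatase gene Dusp1 lower (−0.68 ± 0.050). Of 14 genes in the heat shock list, which holds heat shock protein and co-chaperone genes and Hmox1, 4 rose and 5 fell (camera adjusted p = 0.454). The inducible chaperone gene Hspa1b fell from 160.3 ± 1.83 to 36.4 ± 1.61 CPM (−2.14 ± 0.046, adjusted p = 8.05e-26, edgeR), and it shares most of its sequence with Hspa1a (−1.46 ± 0.096), a gene named here after its value was seen. Of 41 oxidative phosphorylation subunit genes 16 rose and 8 fell (17 and 9 adjusted over the list alone; camera adjusted p = 0.208, and 0.0307 without control replicate 1). The count that rose was 7 with library totals, and 10 with DESeq2, with GC content and transcript length trends removed, and without control replicate 2 or 3 or senescent-medium replicate 3, and the count that fell was 5 without control replicate 1 or senescent-medium replicate 2 or 3. Uqcrq rose by 0.43 ± 0.051 and Sdha changed by −0.29 ± 0.037. Of 13 mitochondrially encoded protein genes 7 rose and 3 fell (camera adjusted p = 0.108), and 1 fell without control replicate 3 or with GC content and transcript length trends removed; mt-Nd5 (0.45 ± 0.040) and mt-Nd6 (0.47 ± 0.034) rose. Mitochondrial genes took 2.59% to 2.82% of counts in the control and 2.94% to 3.00% in the senescent-medium libraries. For the early response, heat shock and mitochondrially encoded lists the counts adjusted over the list alone were the same.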

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

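Tests with GC content and transcript length trends removed, or without the most abundant feature, were added after the data were seen; the other alternatives were planned. The main count of 7251 changed genes (edgeR) stayed between 5610 and 7402 under the other tools, scalings, filters and the stricter threshold of 0.01, and between 6404 and 7099 with 1 library left out. DESeq2 called 6131 genes, of which 6118 were shared with the main calls, all in the same direction. Requiring an absolute log2 fold change of at least 1 left 864 genes, 385 higher and 479 lower, and testing against a 1.2-fold change (glmTreat) left 2948, 1457 higher and 1491 lower; both ask for larger changes by construction. With library totals alone 2589 genes were higher and 4813 lower (35.0% higher against 49.7%), and the median of all genes shifted by −0.081. Camera called 13 lists with the preset correlation, and 13 with library totals, with the stricter filter and with the GC and length trends removed. It called 11 to 14 with 1 library left out, and 5 with an estimated correlation. These 5 were both cell cycle lists and the ATF4, endoplasmic reticulum and glycolysis lists. An estimated correlation also leaves camera few residual degrees of freedom, so a lost call need not mean correlated genes. Fry called 24 lists; its p tests whether a list's genes move on balance one way and does not compare them with other genes.

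With the replicate number as a replicate block, 7402 genes (3704 higher, 3698 lower) and 13 lists passed, and no named gene or list changed its call. Equal numbers gave no clear sign of pairing. Deviations from the group means correlated across genes between −0.046 and 0.027 over the 9 pairs of libraries. Pairs with the same number gave 0.019, 0.0019 and 0.026, and not every library correlated best with its own number. Such weak correlations cannot exclude a shared culture or donor.

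Of the 79 named genes 73 kept direction and call in all settings. Ly6a changed sign, to −0.048 with library totals and −0.036 with the GC and length trends removed, in both cases short of the threshold; the cause was not tested. Cdkn1a lost its call with library totals, and Il6 with DESeq2 and with 3 of the single libraries left out. Isg15 and Ifit1 lost theirs with a control library left out, but not with a senescent-medium library left out, which leaves as few samples. In simulated data at these library sizes 50% of 1.2-fold and 70% of 1.5-fold changes were recovered. Far fewer genes were changed there than were called in the data, so these shares need not hold for the real comparison.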

Other observations

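The lists of hypertonicity, Wnt, zinc and iron genes, the chemokine and ribosomal protein families, and the tests on the hypertonicity and interferon patterns were chosen only after the results were seen, as was the look at replicate spread, although leaving out each library was planned; the removal of GC and length trends was added after the data were seen, and what it and the planned test of other splits would show was written down before they were run. Of 16 tested chemokine genes, many of them in the fixed lists, 9 fell and 3 rose under the main scaling and with library totals. The median log2 fold change under the main scaling was −0.76. With DESeq2 or limma-voom 9 fell and 2 rose. The family was not tested as a set. Outside the fixed lists Ccl9, Ccl11 and Cxcl3 fell and Cxcl14 rose. Cxcl3, a neutrophil attractant, was low and fell from 1.45 ± 0.456 to 0.233 ± 0.0375 CPM, by 2.61 on the log2 scale (adjusted p = 1.12e-05, edgeR). Cxcl12 and Cxcl14 rose by 0.88 and 0.89. Cxcl9, the other one to rise, was also low, at 0.396 ± 0.166 CPM in control and 0.960 ± 0.635 CPM in senescent macrophage medium, with overlap between libraries. Of 9 tested Wnt/beta-catenin feedback targets 4 fell and 0 rose: Notum (−1.92 ± 0.15), Lgr5 (−1.29 ± 0.22), Axin2 (−1.02 ± 0.25) and Nkd2 (−0.63 ± 0.075). Exon overlaps with other genes were not looked up for these 4, so shared reads are not excluded. These genes were named after their values were seen.

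Of 11 iron handling genes 6 rose and 0 fell, among them the iron exporter gene Slc40a1 (1.01 ± 0.112 to 3.47 ± 0.427 CPM, log2 fold change 1.77 ± 0.24), the ferritin light chain gene Ftl1 (0.77 ± 0.036), which has near-identical copies, and the transferrin receptor gene Tfrc (0.60 ± 0.056). Of 6 zinc and metallothionein genes 3 rose, Mt1, Mt2 and the zinc exporter gene Slc30a1 (0.49 ± 0.084), and the importer gene Slc39a10 fell (−0.76 ± 0.055). Of 83 genes picked by the symbols of cytosolic ribosomal proteins, 47 rose and 3 fell, with a median of 0.18. The family so picked includes paralogs and copies such as Rps3a2, and the 3 that fell were Rpl5 and the paralogs Rpl7l1 and Rpl22l1. The median was 0.10 with library totals (29 higher), 0.11 with GC content and transcript length trends removed (43 higher) and 0.14 to 0.26 with 1 library left out (34 to 63 higher). These genes too were named after their values were seen, and as the lists were made then, no test of them as sets is given.

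Genes that cells induce in hypertonic medium were lower in senescent macrophage medium. All 12 listed ones fell, with a median log2 fold change of −0.75, including Slc5a3, the betaine transporter gene Slc6a12 (−1.84 ± 0.15), the taurine transporter gene Slc6a6 (−0.70 ± 0.034) and Nfat5 (−0.58 ± 0.054), the transcription factor of that response. Reads that Slc5a3 and Hspa1b share with other genes do not account for the pattern, since the median without these genes was −0.64. Exon overlaps were looked up only for the named genes, so shared reads are not excluded for members outside them. The scaling does not account for the pattern either, as the median nearest 0 under other scalings was −0.73. The other 11 tested heat shock protein and co-chaperone genes, without Hspa1a and Hspa1b, moved both ways with a median of −0.0072 (SD 0.27, lowest −0.52). A general fall of heat shock genes therefore does not account for the pattern. A candidate explanation is that senescent macrophage medium had a lower osmolality than control macrophage medium, as a hypothesis that the fall of all 12 genes prompted and that cannot be told apart from other differences between the media without a measurement of them. The list was made after Slc5a3 and Hspa1b were seen to fall.

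Interferon-stimulated genes were higher by different amounts in the 3 senescent-medium libraries. Replicate 1 alone does not account for the pattern, since 44 of 48 members were higher without it. Macrophages or their RNA carried over with the medium are argued against as the source of the rise, since such cells bring their abundant transcripts with them: the 6 of 9 leukocyte markers in the table with a higher mean rose by a summed 6.99 CPM (SE 1.57), against 683 CPM (SE 165) for the interferon-stimulated genes, although Lyz2, abundant in macrophages, did rise, and the median of the tested markers, as that of the interferon list, was highest in replicate 1; the cell sort came before the medium was added and would not remove them. Interferon or nucleic acid in the conditioned medium stays open, as untested, as does an interferon made by the stem cells themselves: 0 interferon genes were tested and higher, and 1 (Ifnz) was in the table at all, but genes with few reads may be left out of the table.

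About 1 gene in 2 passed the threshold, most by a small fold. A trend with GC content or transcript length is argued against as the whole cause, since 7331 genes passed after both were removed. The common biological coefficient of variation was 4.22%, and libraries of a medium that shared a cell isolate and a medium pool could give so low a spread; the labels do not say, so this cannot be told apart from a change of that breadth.

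The real grouping gave 7251 genes in edgeR (7996 at an unadjusted p under 0.05, 7170 in limma-voom). The highest of the 9 other splits of the 6 libraries gave 0 in edgeR, with 97 to 214 at an unadjusted p under 0.05 and 0 in limma-voom. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split puts libraries of both media in each group, so the difference between media adds to the spread within groups. These splits therefore cannot show how many genes would pass without a difference between media. For lists the real grouping gave 13 camera calls with the preset correlation and the highest other split 11, the others 8 to 11. With an estimated correlation the real grouping gave 5 and the others 0, and here too 1 of 10 is the smallest share possible. Part of the difference between media remains between the groups of the other splits, so their list calls are no baseline either.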
